A study of Mus musculus with 18 samples.

How the data were processed

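RNA was sequenced from Input and Positive fractions of brain, retina and choroid, 3 libraries each, per the labels with a directional library kit. Per the labels the Input is a portion of the supernatant set aside before the pull-down, so Input and Positive libraries of the same number and tissue come from the same homogenate. As a check, the deviations of same-numbered libraries from their group means correlated above 0.1 in 8 of 9 pairs (lowest 0.0014, highest 0.281). In Brain and Choroid each Input correlated most with the Positive of its own number. Retina Input 1 correlated more with Positive 3 (0.18) than with Positive 1 (0.102). Retina Input 3 correlated more with Positive 2 (0.0514) than with Positive 3, so in Retina the check did not single out the pairs. The labels name 3 biological replicates per tissue and do not state the number of animals.

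The deposited tables, 1 per tissue, hold raw values that are expected counts per the file headers and their fractional form, and normalized values on a log2 scale that the authors computed. The aligner and the counting program, and whether strand was used in counting, are not given in the sources used here. The submitters' processing notes name mm10 and DESeq without a version. The normalized values were recovered as log2 of the raw value over a per-sample factor, minus the Input median, within 1e-04 for 100% of Brain and Retina and 99.998% of Choroid values. Per the file headers, a gene was kept when its raw value was at least 50 in all samples of at least 1 of the 2 fractions. Brain lists 13957 genes (609 met this in Input alone, 528 in Positive alone and 12820 in both), Retina 12827 (874, 329 and 11624) and Choroid 7569 (4439, 137 and 2993). Genes below this minimum in both fractions were not analysed here. Totals refer to listed genes and are not full library depths.

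Symbols and Entrez identifiers are the authors', and some symbols are older names (Ppap2a for Plpp1, Ptrf and Sdpr for Cavin1 and Cavin2, Gpr116 for Adgrf5, Eltd1 for Adgrl4, Beta-s for Hbb-bs, Adc for Azin2). Coordinates came from the RefSeq annotation of GRCm38.p6, the assembly of mm10, which held 99.71%, 99.72% and 99.85% of the identifiers of the 3 tables. Reads of near-identical copies, such as H2 class I and alpha-globin genes, can be split by counting, so single values of these genes are uncertain.

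The expected counts were rounded to whole numbers. Each tissue was fitted apart with edgeR 4.0.16 (TMM scaling, filterByExpr with a minimum count of 10, which removed no gene, and the quasi-likelihood F test on 4 residual degrees of freedom). Differences between tissues in Positive over Input were tested as interactions in a fit of all 18 libraries over the 7270 genes listed in the 3 tables. Positive fractions were compared with each other in a fit of 9 libraries over the same genes, across tables that had been filtered separately. Adjusted p-values are Benjamini-Hochberg values over the tested genes, with a threshold of 0.05. Levels are TMM-normalised counts scaled to library size (CPM) with SD over 3 libraries, and SE belongs to the fitted log2 fold change. Before the data were examined, the groups, comparisons, tests, thresholds, alternative settings and the rule for named genes were fixed.

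Fixed gene lists covered endothelial classes, other cell types and RNA classes (28 lists, of which 27 held 282 symbols, 259 of them matched, and 1 held the ribosomal protein genes). A list of mitochondrially encoded transcripts was not analysed here. Some genes stand in more than 1 list. Lists with at least 3 measured members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, which assumes little correlation between members, again with an estimated correlation and again on ranks, with Benjamini-Hochberg adjustment over the lists of a comparison. The count of members past the threshold was also taken with p-values adjusted over the list alone, and is given where the 2 counts differ.

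The named genes are, per tissue, the 10 with the largest increase and the 10 with the largest decrease among genes past the threshold with all Positive values on the same side of all Input values and a mean level at or above the median, with predicted, clone and pseudogene symbols left out. Of each list, the first 2 measured members and the 2 with the largest change were added. For differences between tissues and between Positive fractions the rule took 8 genes each way, and for the shared genes the 10 with the largest smallest fold change. List members given as the exceptions to a direction were chosen after their values were seen. Some genes that the rule picked are not reported here.

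Alternative settings fixed at that time were DESeq2 size factors, no filter, a stricter filter at the median level, the DESeq2 1.42.0 Wald test, leaving out each library, the replicate number as a block, an adjusted p under 0.01, and a log2 fold change of at least 1. Added after seeing the data were the authors' factors, scaling on the pan-endothelial genes, thinning of Brain and Retina to Choroid depth, leaving out Lars2 and Rn45s, and all genes shared by Brain and Retina. The tests were tested on simulated data drawn with each fit's own levels and dispersions, in which 200 genes were changed. Changes of 2-fold were recovered at 92% (Brain), 76% (Retina), 32% (Choroid), 56% (Choroid minus Brain) and 68% (Choroid Positive against Brain Positive), with 6.53%, 5.59%, 10.2%, 6.43% and 3.95% of calls false. The simulated list that was moved was called, and 0 of 20 unchanged lists were called by camera. Simulated genes were drawn independently of each other, so this could not test list calls where members are correlated. R 4.3.3, Python 3.11.15 and matplotlib 3.10.9 were used.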

Results

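Ribosome-bound RNA from endothelial cells was compared with whole-tissue RNA in brain, retina and choroid of mice carrying Cdh5(PAC)-cre/ERT2 and NuTRAP. Cdh5(PAC)-cre/ERT2 is a tamoxifen-inducible recombinase driven by the promoter of vascular endothelial cadherin, and NuTRAP is a reporter that puts GFP on the ribosomal protein L10a once it has been recombined. An antibody against GFP then isolates tagged ribosomes with the RNA they carry, a method called translating ribosome affinity purification (TRAP). The Positive fraction held the RNA on the beads, and the Input fraction was RNA set aside from the same homogenate before the pull-down. The 3 tissues each gave 3 Input and 3 Positive libraries, 18 libraries in 6 groups. The labels call them biological replicates without saying how many animals each holds, so p-values measure the spread between these samples, which may be partly technical.

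Listed genes summed to 28128866, 42689793 and 43219831 estimated counts in Brain Input and 31111437, 40112343 and 38326386 in Brain Positive. Retina Input held 36157140, 29059581 and 20915469 and Retina Positive 22126763, 12325658 and 26069649. Choroid libraries were much shallower, at 3467816, 2018126 and 10031274 in Input and 2717264, 713733 and 1679648 in Positive. In counts simulated with the levels and the spread of each fit, genes changed 2-fold were recovered at 92% in Brain, 76% in Retina and 32% in Choroid, and genes changed 4-fold at 100%, 100% and 94%. These simulations changed 200 genes per fit, far fewer than passed in the data, and recovery under Benjamini-Hochberg adjustment depends on that number. Differences of 2-fold in Choroid may therefore be missed, at a rate that these percentages do not fix. In Choroid Positive replicate 2, Rn45s, the ribosomal RNA precursor, and Lars2, a mitochondrial leucyl-tRNA synthetase gene, took 13% and 3.71% of the listed counts.

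Pan-endothelial genes made up 0.0306% ± 0.00147 (SD, n = 3) of listed counts in Brain Input and 0.843% ± 0.0225 in Brain Positive. In Retina the share went from 0.0298% ± 0.00301 to 0.603% ± 0.261, with Positive replicate 3 at 0.904% and replicates 1 and 2 at 0.448% and 0.455%. Choroid Input already held 0.444% ± 0.123 and Choroid Positive 2.78% ± 0.517. Fibroblast genes moved in opposite directions in Brain and Choroid, from 0.015% ± 0.000535 to 0.214% ± 0.0423 in Brain and from 0.374% ± 0.0585 to 0.0553% ± 0.0124 in Choroid. Genes of the retinal pigment epithelium, the pigmented layer between retina and choroid, took 3.59% ± 0.873 of Choroid Input and 0.294% ± 0.0716 of Choroid Positive. Photoreceptor genes took 5.77% ± 0.565 of Retina Input and 5.52% ± 1.39 of Retina Positive, a difference within the spread between replicates. A two-sided exact permutation test of 3 against 3 libraries cannot go below p = 0.1, so the shares are given with their spread alone.

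**Figure D1:**
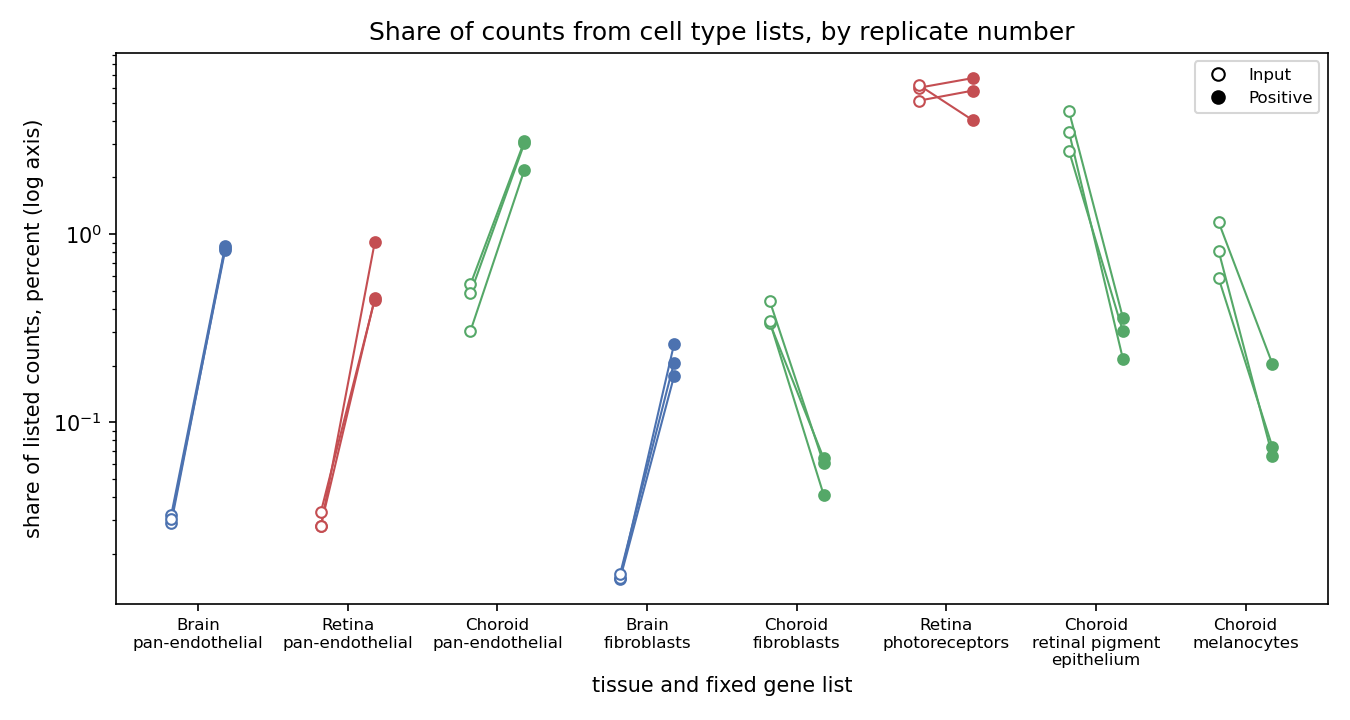
Share of the listed counts (percent, log axis) taken by a fixed gene list in each Input (open) and Positive (filled) library, with lines joining libraries of the same replicate number. Pan-endothelial shares were higher in Positive in 9 of 9 joined libraries, while Retina photoreceptor shares overlapped between fractions at means of 5.77% and 5.52%.

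In brain, the pull-down asked which transcripts ribosomes of the endothelium carried relative to the whole tissue. Cdh5 itself (Entrez 12562, chromosome 8, 104101625 to 104144502 on mm10), which encodes vascular endothelial cadherin, rose from 10.3 ± 0.703 to 358 ± 18.2 normalised CPM (counts scaled to library size, SD, n = 3). That was a log2 fold change of 5.11 ± 0.085 (SE) with an adjusted p of 1.1e-10 by edgeR's quasi-likelihood test. The largest increases among well-expressed genes were in the transcription factor genes Foxf2 (5.55 ± 0.15, 46.8-fold, Entrez 14238), Sox18 (5.54 ± 0.16) and Erg (5.41 ± 0.099), in Akr1c14, a steroid dehydrogenase gene (5.53 ± 0.19), and in Gkn3 (5.51 ± 0.16). Slc52a3, a riboflavin transporter gene, Pglyrp1, She, Ly6a and Tmem252 followed at 5.46, 5.45, 5.38, 5.37 and 5.37. The largest decreases among well-expressed genes were led by myelin genes, with Ermn at -2.61 ± 0.29, Mog at -2.40 ± 0.29 and Mag at -2.32 ± 0.28.

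All 20 pan-endothelial genes rose in brain (median log2 5.12, camera adjusted p = 3.32e-64, and adjusted p = 0.00814 with an estimated correlation). The 20 blood-brain and blood-retina barrier genes rose as well (median 4.27, adjusted p = 1.66e-34, and 0.00814 with an estimated correlation). They included Mfsd2a, a lipid transporter gene that restrains transcytosis (2.86 ± 0.075), Slc2a1, the glucose transporter gene (4.44 ± 0.092), and Abcb1a, an efflux pump gene (5.26 ± 0.13). So did 15 of 15 genes of the Wnt/beta-catenin pathway of central nervous system vessels (median 3.71, adjusted p = 2.56e-21, and 0.00814 with an estimated correlation), among them the receptor gene Fzd4 (3.86 ± 0.12) and its co-receptor Tspan12 (1.57 ± 0.08). All 13 arterial genes rose, led by Gkn3, Bmx (5.43) and Sema3g (5.27), with adjusted p = 2.26e-14, and adjusted p = 0.0543 with an estimated correlation. Of 9 venous genes 8 rose, such as Slc38a5 (5.21) and Vwf (4.73), with adjusted p = 8.45e-08, and adjusted p = 0.142 with an estimated correlation. Of 9 caveolar and transcytosis genes 8 rose, among them Cav1 (4.67), with adjusted p = 8.47e-13, and adjusted p = 0.0685 with an estimated correlation. The 9 fenestrated endothelium genes all rose, though Plvap, which encodes the diaphragm protein of fenestrae, rose little (0.94 ± 0.16, from 22.9 to 43.8 CPM), with adjusted p = 0.000396, and adjusted p = 0.0744 with an estimated correlation. Of 8 tip cell genes 6 rose and Apln fell (-0.45 ± 0.14, adjusted p = 0.0523 and 0.0592 without Brain Positive replicate 1 or 2), with adjusted p = 7.48e-05, and adjusted p = 0.144 with an estimated correlation. The 11 genes of MHC class I presentation rose, including B2m (3.53 ± 0.10), with adjusted p = 8.47e-13, and adjusted p = 0.139 with an estimated correlation. H2 class I genes are near-identical copies whose reads the counting could split, so single values such as H2-D1 (3.05) are uncertain.

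Genes of other brain cells fell. All 12 neuronal genes fell (median -1.29, Snap25 -1.05 ± 0.075, Camk2a -1.62 ± 0.096), with adjusted p = 1.57e-06, and adjusted p = 0.139 with an estimated correlation. Of 10 oligodendrocyte lineage genes 8 fell and Mal and Cldn11 rose (adjusted p = 0.0181, and adjusted p = 0.584 with an estimated correlation). Of 12 microglial genes 11 fell, such as Cx3cr1 (-1.66 ± 0.19), and Tmem119 rose (adjusted p = 0.032, and adjusted p = 0.612 with an estimated correlation). Of 11 astrocyte genes 9 fell, such as Aqp4 (-1.65 ± 0.13), and 2 rose (adjusted p = 0.0418, and adjusted p = 0.503 with an estimated correlation). The 8 nuclear and long non-coding RNAs fell, among them Malat1 (-1.56 ± 0.13), with adjusted p = 0.00642, and adjusted p = 0.503 with an estimated correlation. Fibroblast genes went the other way: 8 of 8 rose (median 4.10, adjusted p = 3.29e-07, and adjusted p = 0.195 with an estimated correlation), with the collagen genes Col1a1 at 4.33 ± 0.17 and Col1a2 at 4.39 ± 0.16. Mural genes split, with 5 of 12 higher, such as Vtn (3.58) and Tagln (2.59), and 6 lower, such as Rgs5 (-0.63, adjusted p = 0.0606 with the authors' factors, and 0.101, 0.147, 0.149 and 0.143 without Brain Input replicate 2 or 3 or Brain Positive replicate 2 or 3), and their median of -0.32 and mean of 0.476 differed in sign (adjusted p = 0.497). Of 80 ribosomal protein genes 79 rose (median 0.809, adjusted p = 5.12e-06, and adjusted p = 0.612 with an estimated correlation). Rpl10a, which encodes the protein tagged in TRAP, ranked 1 of 80 at 2.17 ± 0.064, next to Rps27l at 2.16.

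Among the remaining lists in brain, the 3 measured photoreceptor genes rose from very low levels, Pde6a from 0.451 to 5.12 CPM (adjusted p = 0.309 for the list). Of 7 pigment epithelium genes 3 rose, such as the retinol receptor gene Stra6 (4.59 ± 0.098), and 4 fell, and of 9 choroid plexus genes 2 rose and 7 fell, such as Ttr (-2.22). The 4 erythroid genes fell, with single values such as Hba-a2 (-2.21, and -1.22 without Brain Input replicate 1) uncertain because reads of near-identical globin genes can be split. Of 9 immediate early genes 4 rose, such as Atf3 (2.81), and 3 fell, such as Fos (-0.85), and the list's median of -0.0108 turned to 0.000392 with DESeq2 size factors and 0.0454 with the authors' factors. Lymphatic genes (2 higher, 2 lower), skeletal muscle genes (1 and 1), retinal interneuron and ganglion cell genes (1 and 3), melanocyte genes (0 and 2) and platelet genes (0 and 1) gave no call as lists. Lymphatic, interneuron and pigment epithelium lists had medians (-0.514, -0.258 and -1.24) opposite in sign to their means (0.925, 0.387 and 0.298). In all, 10896 of 13957 genes passed, 5352 higher and 5544 lower, and 2471 and 2136 of these by at least 2-fold. Counts adjusted over the list alone equalled those adjusted over all genes in each list.

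In retina, Cdh5 rose from 2.92 ± 0.855 to 284 ± 134 CPM (SD, n = 3), a log2 fold change of 6.63 ± 0.40 (98.9-fold, adjusted p = 5.12e-05 by edgeR). Gpr116, an adhesion receptor gene (6.62 ± 0.40), Abcb1a (6.52 ± 0.38), Eltd1 (6.52 ± 0.44), the angiopoietin receptor gene Tek (6.51 ± 0.36) and Tie1 (6.43 ± 0.44) followed, then Robo4, Ly6c1, Cldn5 and Vwf at 6.42, 6.40, 6.39 and 6.39. Among genes at or above the median level, the decreases were led by genes of cone photoreceptors, the daylight receptors of the retina. Some genes below that level, such as C1qa (-2.73), fell by more than most of them. The cone opsin genes Opn1mw and Opn1sw stood at -3.08 ± 0.17 and -2.10 ± 0.15, the cone phosphodiesterase genes Pde6h and Pde6c at -2.93 ± 0.16 and -2.12 ± 0.10, and the cone transducin genes Gnat2 and Gngt2 at -1.87 ± 0.14 and -1.72 ± 0.16. Nrsn1 (-1.45), the ferritin gene Fth1 (-1.41), Pigm (-1.24) and Zbtb6 (-1.20), which are not cone genes, followed. Opn1mw went from 111 ± 8.68 to 12.97 ± 3.01 CPM. The rod transducin gene Gnat1, at 10340 ± 1096 in Input and 11480 ± 2721 in Positive, did not pass (0.15 ± 0.20, adjusted p = 0.613).

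Of 20 pan-endothelial genes 19 rose in retina, and 20 adjusted over the list alone (median 6.19, camera adjusted p = 2.36e-65, and adjusted p = 0.117 with an estimated correlation). The exception was the VEGF receptor gene Kdr (155 CPM in Input, 264 in Positive). Of 20 barrier genes 18 rose, including Mfsd2a (5.42 ± 0.42) and Slc2a1 (3.05 ± 0.32), and Slc38a3 and Slc6a6 did not pass (adjusted p = 9.04e-40, and adjusted p = 0.118 with an estimated correlation). Of 15 Wnt/beta-catenin genes 14 rose (adjusted p = 1.05e-20, and adjusted p = 0.185 with an estimated correlation), such as Sox17 (6.30 ± 0.49). Of 13 arterial genes 12 rose, with Gkn3 at 6.41, and Jag1 fell (adjusted p = 1.97e-18, and adjusted p = 0.164 with an estimated correlation). Of 8 venous genes 7 rose, with Slc38a5 at 5.62 (adjusted p = 1.98e-13, and adjusted p = 0.117 with an estimated correlation). Of 9 caveolar genes 8 rose (adjusted p = 1.48e-14, and adjusted p = 0.117 with an estimated correlation), and so did 3 of 3 tip cell genes (adjusted p = 2.31e-05, and adjusted p = 0.186 with an estimated correlation). Of 8 fenestrated genes 5 rose, and 6 adjusted over the list alone, with Plvap at 0.66 ± 0.17, a call lost without Retina Input replicate 2 or 3 or Retina Positive replicate 1 at adjusted p = 0.0948, 0.0719 and 0.0572 (list adjusted p = 1.61e-05, and adjusted p = 0.285 with an estimated correlation). The 10 MHC class I genes rose (median 2.71, adjusted p = 2.24e-12, and adjusted p = 0.189 with an estimated correlation).

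Of 17 photoreceptor genes in retina the cone genes Opn1sw, Opn1mw and Arr3 fell and 14 did not pass (adjusted p = 0.00286, 0.111 by the rank-based test, and adjusted p = 0.497 with an estimated correlation). Of 8 microglial genes 6 fell, with the complement gene C1qa at -2.73 ± 0.32 (adjusted p = 3.27e-07, and adjusted p = 0.117 with an estimated correlation). Of 12 neuronal genes 7 fell, and 8 adjusted over the list alone, by small amounts such as Tubb3 (-0.51), with adjusted p = 0.004, and adjusted p = 0.309 with an estimated correlation. Of 7 nuclear and long non-coding RNAs 4 fell, such as Malat1 (-0.86 ± 0.11), with adjusted p = 0.00432, and adjusted p = 0.309 with an estimated correlation. Of 11 interneuron and ganglion cell genes 4 rose, and 7 adjusted over the list alone, such as the bipolar cell gene Pcp2 (1.17 ± 0.20, list adjusted p = 0.153). Ribosomal protein genes fell slightly as a list (median -0.128, 15 of 80 lower and 4 higher, 14 and 4 adjusted over the list alone, adjusted p = 0.0156, and adjusted p = 0.706 with an estimated correlation), while Rpl10a rose (0.67 ± 0.12) and ranked 2 of 80 behind Rps27l at 0.79. Of the 4 oligodendrocyte genes Mal rose (4.98 ± 0.66), and of 11 Mueller glia and astrocyte genes Gja1 rose (3.67 ± 0.36) and 4 fell. The 6 mural genes gave 0 calls by edgeR, 0 at an unadjusted p under 0.05 and 0 by DESeq2.

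The remaining retina lists gave no call. Pigment epithelium genes had 4 of 8 lower and Stra6 higher (4.72 ± 0.33), and the list passed with the replicate number as a block (adjusted p = 0.0197 against 0.382). Melanocyte genes had 2 of 3 lower, choroid plexus genes 2 of 8 lower, fibroblast genes 1 of 3 lower (Pdgfra, adjusted p = 0.0635 with the block, and 0.0822, 0.132, 0.105, 0.0803 and 0.0582 without Input replicate 1, 2 or 3 or Positive replicate 2 or 3) and skeletal muscle genes 1 of 3 lower, the latter with a median of 0.153 and a mean of -0.175. Immediate early genes had 3 of 9 higher, such as Dusp1 (0.99), lymphatic genes 1 higher and 1 lower, 2 and 1 adjusted over the list alone, and neither of 2 erythroid genes passed. The platelet gene Gp1bb (-0.47 ± 0.16) passed adjusted over the list alone and with the replicate block (adjusted p = 0.0386), but not in the unblocked fit over all genes. In all, 3352 of 12827 genes passed, 1961 higher and 1391 lower, and at least 2-fold in 1075 and 95. Without Retina Input replicate 2 the count was 1836 and without Retina Input replicate 1 it was 2048.

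In choroid, the vascular layer behind the retina, Cdh5 rose from 173 ± 59.2 to 1332 ± 252 CPM (SD, n = 3), a log2 fold change of 2.94 ± 0.29 (7.67-fold, adjusted p = 1.56e-05 by edgeR). Plvap (Entrez 84094, chromosome 8, 71497753 to 71511769) rose from 1062 ± 348 to 9170 ± 828, or 3.11 ± 0.32. The increases were led, among genes at or above the median level, by Cytl1 (3.28 ± 0.44), the semaphorin gene Sema3g (3.22 ± 0.44), the potassium channel gene Kcnq1 (3.18 ± 0.41), Esm1 (3.17 ± 0.25) and Gimap1 (3.16 ± 0.24), with Mall, Fam167b, Acer2 and Igfbp3 at 3.14, 3.11, 3.11 and 3.07. Genes of the pigment epithelium and its visual cycle were among the largest decreases at that level. Rdh5, a retinol dehydrogenase gene, stood at -4.04 ± 0.34, Rlbp1, a retinaldehyde-binding protein gene, at -3.97 ± 0.37 and the opsin gene Rrh at -3.95 ± 0.32. The zinc transporter gene Slc39a12 had the lowest value of these genes, -5.39 ± 0.62, followed by Ermn (-4.33), Iqgap2 (-4.30), Slc6a20a (-4.21), Pla2g5 (-4.09), Pon1 (-4.07) and Adc (-3.99).

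All 19 measured pan-endothelial genes rose in choroid (median 2.80, camera adjusted p = 3.28e-27, and adjusted p = 0.107 with an estimated correlation), as did 9 of 9 fenestrated genes (median 2.82, Cd24a 2.94 ± 0.26, adjusted p = 2.15e-13, and adjusted p = 0.107 with an estimated correlation). Barrier genes split: 6 of 17 rose, such as Foxf2 (1.51 ± 0.33), and 6 fell, such as the monocarboxylate transporter gene Slc16a1 (-3.88 ± 0.35), the amino acid transporter gene Slc38a3 (-3.18 ± 0.37) and Mfsd2a (-2.33 ± 0.53). Slc16a1 stood at 1069 ± 334 CPM in Choroid Input, where pigment epithelium genes took 3.59% of the listed counts. Which cells gave the Input transcripts of these transporters was not tested. Slc2a1 did not pass (0.07 ± 0.23, adjusted p = 0.836), and the barrier list gave no call (adjusted p = 0.47, with a median of 0.116 and a mean of -0.418). Of 11 Wnt/beta-catenin genes 5 rose, and 6 adjusted over the list alone, with Tspan12 at 2.49 ± 0.31 (adjusted p = 0.032, and adjusted p = 0.445 with an estimated correlation). Of 9 caveolar genes 8 rose and Mfsd2a fell (adjusted p = 2.37e-06, and adjusted p = 0.107 with an estimated correlation). Of 11 arterial genes 9 rose (adjusted p = 4.11e-06, and adjusted p = 0.107 with an estimated correlation), and of 6 venous genes 4 rose, and 5 adjusted over the list alone, while Nr2f2 fell (-1.18), with adjusted p = 0.00177, and adjusted p = 0.235 with an estimated correlation. Of 7 tip cell genes 4 rose and 3 fell, among them Pgf (-3.44 ± 0.40), with adjusted p = 0.0159, 0.392 by the rank-based test, 0.0654 without Choroid Positive replicate 2, and adjusted p = 0.273 with an estimated correlation. The 10 MHC class I genes rose (median 1.40, adjusted p = 1.42e-05, and adjusted p = 0.209 with an estimated correlation). Of 6 immediate early genes 5 rose, such as Ier2 (2.42 ± 0.25), Dusp1 (2.17 ± 0.28) and Jun (2.08 ± 0.22), with adjusted p = 5.38e-05, and adjusted p = 0.107 with an estimated correlation.

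Genes of most other cell types fell in choroid. All 9 pigment epithelium genes fell (median -3.67, Rpe65 -3.67 ± 0.36, Lrat -3.76 ± 0.23, adjusted p = 4.53e-15, and adjusted p = 0.107 with an estimated correlation). The 8 melanocyte genes fell, with the pigment synthesis genes Tyr and Tyrp1 at -3.04 and -2.80 (adjusted p = 4.62e-07, and adjusted p = 0.18 with an estimated correlation). The 7 fibroblast genes fell, with Lum at -3.75 and Col1a2 at -2.68 (adjusted p = 9.13e-08, and adjusted p = 0.107 with an estimated correlation). Of 10 mural genes 7 fell, with Pdgfrb at -3.47 ± 0.56 (adjusted p = 0.00277, and adjusted p = 0.172 with an estimated correlation). Of 9 microglial and macrophage genes 8 fell, with C1qa at -3.17 (adjusted p = 4.11e-06, and adjusted p = 0.107 with an estimated correlation). Of 13 photoreceptor genes 11 fell (adjusted p = 9.91e-08, and adjusted p = 0.172 with an estimated correlation), and of 8 astrocyte and Mueller glia genes 6 fell (adjusted p = 0.000648, and adjusted p = 0.172 with an estimated correlation). Of 7 choroid plexus genes 6 fell, with Ttr at -3.23 (adjusted p = 1.42e-05, and adjusted p = 0.107 with an estimated correlation). The 3 erythroid genes fell, and that list passed with the replicate block (adjusted p = 0.0092 against 0.0745). Ribosomal protein genes rose slightly as a list (median 0.292, 12 of 80 higher, 2 adjusted over the list alone, adjusted p = 0.0132, and adjusted p = 0.747 with an estimated correlation). Without Choroid Positive replicate 2 that call was lost (median 0.126, 4 higher and 2 lower, adjusted p = 0.247). Rpl10a ranked 1 of 80 at 1.88 ± 0.20, ahead of Rpl7 at 0.97. Lists without a call were neurons (3 of 5 lower, Stmn2 higher at 1.78), retinal interneurons (2 of 4 lower, Rbpms higher at 1.75), the oligodendrocyte lineage (Mal of 5 higher at 2.30), skeletal muscle (2 of 7 lower, 1 adjusted over the list alone), and nuclear and long non-coding RNAs (Neat1 of 6 lower). Of 2 lymphatic genes 1 rose and 1 fell.

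In all, 2767 of 7569 genes passed in choroid, 1236 higher and 1531 lower, and at least 2-fold in 818 and 1320. The authors' minimum of 50 counts was met by Input alone in 4439 of the listed genes and by Positive alone in 137, and Positive was also the shallower fraction.

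**Figure D2:**
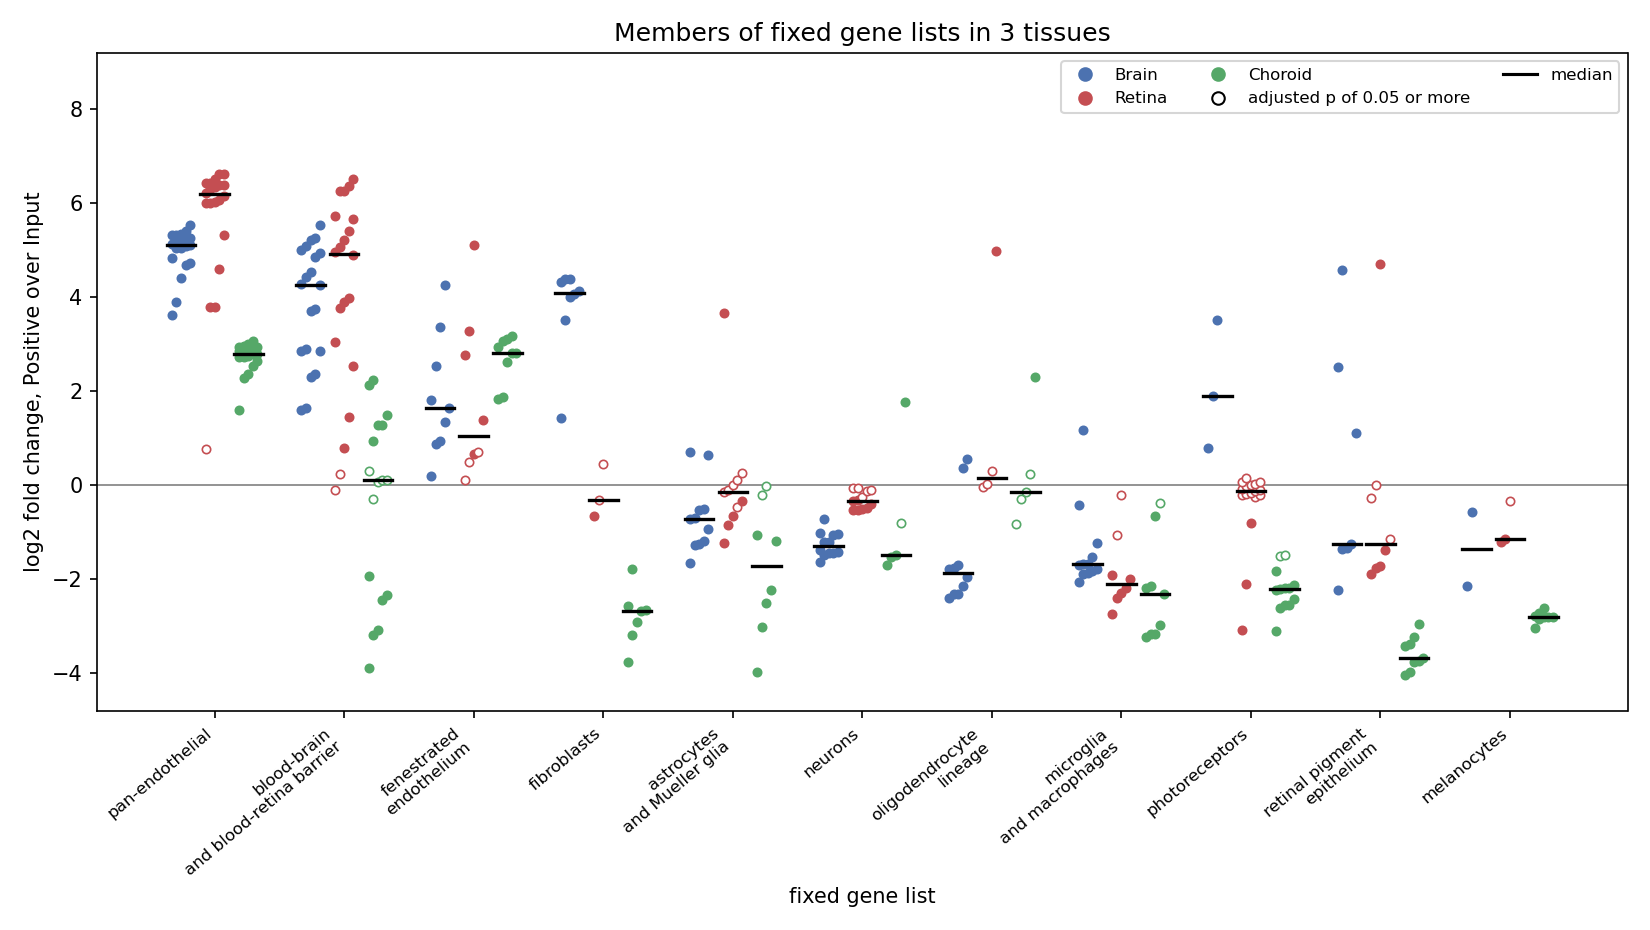
Log2 fold change of Positive over Input (vertical axis) for each measured member of 11 fixed gene lists in Brain, Retina and Choroid, with filled points for members past an adjusted p of 0.05, open points for the others and bars for medians. Fibroblast genes had a median of 4.10 in Brain and -2.68 in Choroid, and barrier genes had medians of 4.27, 4.93 and 0.116 in Brain, Retina and Choroid.

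Of the 7270 genes listed in the 3 tissues, 686 were higher in Positive in each tissue. The 10 with the largest smallest fold change were Sema3g, Igfbp3, Sox18, Tie1, Notch4, Esam, Cdh5, Ctla2a, Kif26a and Pdgfb. Notch4, a Notch receptor gene, had log2 fold changes of 4.29 ± 0.12, 4.82 ± 0.44 and 2.97 ± 0.30 in Brain, Retina and Choroid (n = 3 per fraction), and Pdgfb, which encodes a growth factor that recruits pericytes, 3.11 ± 0.081, 5.93 ± 0.46 and 2.89 ± 0.21. Lists of 3533, 1542 and 1214 higher genes drawn independently would share 125, and the 3 comparisons share no library. Lower genes numbered 2235, 663 and 1308, of which 153 were shared against 36.7 drawn independently. Another 700 genes passed as higher in Brain and Retina but not in Choroid. Simulated 2-fold changes there were recovered at 32%, with 200 genes changed. Not passing in Choroid is therefore not evidence of no enrichment there. Of the genes higher in Brain and Retina, 107 were lower in Choroid. Without Retina Input replicate 2 and without Retina Input replicate 1, 67 and 82 genes were lower in the 3 tissues.

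Whether enrichment differed between choroid and brain was tested as an interaction over all 18 libraries. Barrier transport genes were less enriched in choroid: Slco1c1, a thyroid hormone and organic anion transporter gene, by -7.16 ± 0.39 on the log2 scale, Slc22a8, another organic anion transporter gene, by -7.11, and Mfsd2a by -4.91 ± 0.56. Slc2a1 differed by -4.18, with 1302 CPM in Choroid Input and 107 in Brain Input, while the Positive fractions did not pass against each other (-0.42 ± 0.30, adjusted p = 0.26). The cells that gave the transporter transcripts of Choroid Input were not told apart, which bears on these differences and on those from retina. Edn3, an endothelin gene, was lower by -7.66 ± 0.53. Aqp1, a water channel gene, was more enriched in choroid by 3.81 ± 0.48, followed by Prickle2 (3.59), the homeobox gene Six3 (3.51) and Mcam (3.40). Of 17 barrier genes 17 were lower (median -4.18, camera adjusted p = 4.68e-15, and adjusted p = 0.0334 with an estimated correlation), and of 8 fenestrated genes 6 were higher, with Plvap at 2.34 ± 0.32 and Cd24a at 2.23 (adjusted p = 0.0136, and adjusted p = 0.437 with an estimated correlation). Of 11 Wnt/beta-catenin genes 8 were lower, with Fzd4 at -3.43 and Apcdd1 at -4.93, and 1 was higher (adjusted p = 0.0123, and adjusted p = 0.437 with an estimated correlation). The 3 measured fibroblast genes were lower, among them Col1a2 (-6.89) and Fbln1 (-7.04), with adjusted p = 1.56e-06, and adjusted p = 0.0257 with an estimated correlation. Of 6 immediate early genes 5 were higher, with Egr1 at 2.42 and Nr4a1 at 2.28 (adjusted p = 0.0129, and adjusted p = 0.354 with an estimated correlation). Photoreceptor (3 of 3), pigment epithelium (4 of 5) and mural (5 of 6) genes were lower, with adjusted p = 0.000944, 0.00604 and 0.0218, and adjusted p = 0.106, 0.354 and 0.386 with an estimated correlation. Venous genes (5 of 5 lower) and nuclear RNAs (3 of 6 higher) passed with the replicate block alone (adjusted p = 0.021 and 0.0432 against 0.0536 and 0.126), and the venous median of -1.84 turned to 0.286 when scaled on the pan-endothelial genes.

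In the same comparison 19 of 19 pan-endothelial genes were lower (median -2.15, adjusted p = 4.67e-05, and adjusted p = 0.437 with an estimated correlation), as were 10 of 10 MHC class I genes (median -2.07, adjusted p = 0.00604, and adjusted p = 0.437 with an estimated correlation). A scaling on the pan-endothelial genes, chosen after the data were seen, moved the median of all genes from -0.0889 to 1.92. Under it the pan-endothelial median was -0.0811, MHC class I turned to 0.00248, barrier genes had 13 of 17 lower and 1 higher (median -2.21), fenestrated genes 8 of 8 higher (3.60), fibroblast genes 3 of 3 lower (-4.89) and ribosomal protein genes turned from -0.223 to 1.81. Photoreceptor genes were 3 of 3 lower under it. Wnt/beta-catenin genes had 5 lower and 3 higher, mural genes 3 lower and 1 higher, and pigment epithelium genes 1 of 5 lower (-0.572). In all 3769 of 7270 genes passed, 1555 higher and 2214 lower (41.3% higher), and 5690 and 314 (94.8% higher) under that scaling. DESeq2 size factors moved the median of all genes to 0.0479.

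Between choroid and retina, enrichment was also lower in choroid for barrier genes. Slco1c1 differed by -8.06 ± 0.40, Mfsd2a by -7.40 ± 0.59, the anion transporter gene Slco1a4 by -5.91, and the amino acid transporter gene Slc7a5 by -5.65. The pigment epithelium list gene Stra6 differed by -7.42. Slc2a1 differed by -2.73, but by -0.15 with an adjusted p of 0.693 when scaled on the pan-endothelial genes. Aqp1 (3.66), Pdia5, a protein disulfide isomerase gene (3.50), Cd24a (2.68) and Plvap (2.67) were more enriched in choroid. Of 17 barrier genes 15 were lower and 1 higher (median -4.35, camera adjusted p = 9.08e-19, and adjusted p = 0.0488 with an estimated correlation). Of 8 fenestrated genes 5 were higher and 1 lower, and 5 and 2 adjusted over the list alone (adjusted p = 0.0213, 0.0703 by the rank-based test, and adjusted p = 0.486 with an estimated correlation). Of 6 immediate early genes 5 were higher, with Jun and Nr4a1 both at 2.02 (adjusted p = 0.00191, and adjusted p = 0.226 with an estimated correlation). Pigment epithelium (4 of 5), astrocyte and Mueller glia (6 of 8), photoreceptor (3 of 3) and fibroblast (3 of 3) genes were lower, with adjusted p = 7.29e-06, 0.0015, 0.0219 and 0.0213, and adjusted p = 0.0892, 0.226, 0.232 and 0.226 with an estimated correlation. Of 80 ribosomal protein genes 51 were higher, and 58 adjusted over the list alone (median 0.729, adjusted p = 3.71e-06, and adjusted p = 0.617 with an estimated correlation).

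Pan-endothelial genes were lower too, 16 of 19 with 1 higher (median -3.32, adjusted p = 6.2e-12, and adjusted p = 0.226 with an estimated correlation), as were venous genes, 5 of 5 (adjusted p = 0.00506, and adjusted p = 0.232 with an estimated correlation), and arterial genes, 7 of 11 with 3 higher (adjusted p = 0.0469, 0.0547 with the replicate block, 0.29 by the rank-based test, 0.106 without Choroid Positive replicate 2, and adjusted p = 0.512 with an estimated correlation). Wnt/beta-catenin and MHC class I genes passed with the block alone (adjusted p = 0.00714 and 0.0494 against 0.0682 and 0.0673), and their medians of -1.01 and -1.03 both turned positive when scaled on the pan-endothelial genes. Scaling on the pan-endothelial genes moved the median of all genes from 0.0727 to 2.54, and the barrier median to -1.99 (11 of 17 lower and 3 higher). It left 2 of 5 pigment epithelium genes lower (-0.571). It turned venous (0.508), arterial (1.10), astrocyte (0.809), photoreceptor (0.437) and fibroblast (0.0605) medians positive. Of 7270 genes 3272 passed, 1581 higher and 1691 lower (48.3% higher), and 6392 and 126 (98.1% higher) under that scaling.

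Between retina and brain, the myelin and lymphocyte protein gene Mal (4.35 ± 0.66), the stress-responsive gene Fam107a (3.71 ± 0.45), Cd34 (2.53 ± 0.32), the phosphodiesterase gene Pde2a (2.44) and Mfsd2a (2.49 ± 0.47) were more enriched in retina. In Retina and Brain Input, Mal was at 14.1 and 338 CPM and Mfsd2a at 2.90 and 28.8 CPM. Between the Positive fractions Mal (-0.09, adjusted p = 0.814), Mfsd2a (-0.69, adjusted p = 0.0683) and Slc2a1 (-0.01, adjusted p = 0.98) did not pass. Kdr (-4.34 ± 0.43), Prom1 (-4.27 ± 0.24), the prostaglandin D synthase gene Ptgds (-4.14 ± 0.48), Igf2 (-3.91 ± 0.32), Pde6a (-3.76 ± 0.39), Alpl, a phosphatase gene (-3.65), and Slc2a1 (-1.45 ± 0.33) were less enriched. Pde6a was nevertheless higher in Retina Positive than in Brain Positive by 8.92, and stood at 0.451 CPM in Brain Input in the Brain fit. The 3 fibroblast genes were lower, with Col1a2 at -3.96 ± 0.27 and Fbln1 at -4.45 (camera adjusted p = 4.74e-05, and adjusted p = 0.0333 with an estimated correlation). The 4 oligodendrocyte genes were higher, with Mbp at 2.12, though Mbp was lower in Retina Positive than in Brain Positive by -3.48 (list adjusted p = 0.00117, and adjusted p = 0.192 with an estimated correlation). Of 80 ribosomal protein genes 72 were lower, and 77 adjusted over the list alone (median -0.951, adjusted p = 7.13e-13, and adjusted p = 0.663 with an estimated correlation). Of 19 pan-endothelial genes 10 were higher, and 11 adjusted over the list alone, and 3 were lower (median 1.10, and 0.531 with 2 higher and 3 lower when scaled on themselves, adjusted p = 0.0216, and adjusted p = 0.737 with an estimated correlation). Barrier genes gave no call (3 of 17 higher and 5 lower, 4 and 5 adjusted over the list alone, adjusted p = 0.821), with a median of 0.163 and a mean of -0.0254, and the median turned to -0.459 when scaled on the pan-endothelial genes. The 3 photoreceptor genes were lower (adjusted p = 0.0266, 0.0532 with the replicate block, and adjusted p = 0.463 with an estimated correlation), and nuclear RNAs passed with the block alone (adjusted p = 0.0361 against 0.0887). Neuronal genes passed without Choroid Positive replicate 2 alone (adjusted p = 0.0448 against 0.077). Of 7270 genes 2170 passed, 802 higher and 1368 lower (37% higher), against 1402 and 885 (61.3% higher) with DESeq2 size factors, which moved the median of all genes from -0.0949 to 0.127, and 74 and 1302 (5.38% higher) with the pan-endothelial scaling, which moved it to -0.553.

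The Positive fractions were also set against each other over the 7270 shared genes, normalised together from separately filtered tables. These comparisons also hold any difference between tissues in RNA carried over from other cells. Plvap averaged 10150 ± 862 CPM in Choroid Positive, 45.5 ± 4.89 in Brain Positive and 19.8 ± 2.54 in Retina Positive (SD, n = 3). Against Brain Positive it was 223-fold higher in Choroid Positive (log2 7.80 ± 0.26, adjusted p = 2.63e-08 by edgeR). Aqp1 was higher by 9.69 ± 0.42, Six3 by 7.56 ± 0.28, Cd24a by 6.21 ± 0.26 and the endothelin receptor gene Ednrb by 5.00 ± 0.21. Lars2 was higher by 6.43 ± 1.55, with 308, 46260 and 1343 CPM in the Choroid Positive replicates, and by 2.15 without replicate 2. Apcdd1, a Wnt inhibitor gene (-5.24 ± 0.26), the synaptic gene Snap25 (-5.14), Igfbp2 (-4.68) and Slco1c1 (-4.63 ± 0.34) were among the lowest. All 8 fenestrated genes were higher, with Ppap2a at 4.98 and Igfbp3 at 4.85 (median 4.72, camera adjusted p = 5.92e-20, and adjusted p = 0.0781 with an estimated correlation), and 8 of 8 also when scaled on the pan-endothelial genes (median 2.93). Of 17 barrier genes 11 were lower, with Mfsd2a at -4.18 ± 0.43 and Spock2 at -4.36 ± 0.27, and 1 was higher (adjusted p = 4.03e-05, and adjusted p = 0.371 with an estimated correlation). Under that scaling 16 of 17 barrier genes were lower, but so were 6367 of all 7270 genes. Of 19 pan-endothelial genes 18 were higher (median 1.59, adjusted p = 4.37e-06, and adjusted p = 0.408 with an estimated correlation), among them Kdr (4.00) and Emcn (3.32), while the scaling on them gave a median of -0.2 and left Cdh5 (1.99 ± 0.28) at 0.18 with an adjusted p of 0.491.

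Pigment epithelium genes remained higher in Choroid Positive than in Brain Positive, 4 of 5 with Rdh5 at 5.37 and Rlbp1 at 4.72 (the other lower adjusted over the list alone, adjusted p = 0.000481, and adjusted p = 0.0781 with an estimated correlation), as did choroid plexus genes, 5 of 6 and 6 adjusted over the list alone (adjusted p = 0.000592, and adjusted p = 0.0805 with an estimated correlation). These lists are not separate, since both hold Ttr and Kcnj13. The largest value of the choroid plexus list was Aqp1 at 9.69. Neuronal genes (5 of 5) and fibroblast genes (3 of 3) were lower (adjusted p = 0.000512 and 0.0123, and adjusted p = 0.358 for both with an estimated correlation). Caveolar (7 of 9), arterial (10 of 11, with Gja5 at 3.66), MHC class I (10 of 10), immediate early (5 of 6) and ribosomal protein genes (44 of 80) were higher with adjusted p = 0.00129, 0.00137, 0.0179, 0.0201 and 0.00282. With an estimated correlation these became adjusted p = 0.371, 0.408, 0.529, 0.371 and 0.676, and each of these medians turned negative (-0.563, -0.696, -0.471, -0.4 and -1.20) when scaled on the pan-endothelial genes. Of 8 astrocyte genes 4 were lower (adjusted p = 0.017, 0.0712 by the rank-based test, and adjusted p = 0.371 with an estimated correlation). Of 7270 genes 3843 passed, 2101 higher and 1742 lower, and 142 and 6367 under that scaling, which moved the median of all genes from 0.0803 to -1.71.

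Against Retina Positive, Choroid Positive was higher in Plvap by 512-fold (SE 0.27 on the log2 scale, adjusted p = 2.53e-08 by edgeR), Ttr, the transthyretin gene, by 6.87 ± 0.62, Cd24a by 6.54, Ednrb by 6.24, Ptgds by 5.90, Ppap2a by 5.63 and Igfbp3 by 5.60. The rod genes Reep6 (-7.14 ± 0.23) and Pde6a (-7.10 ± 0.38) and the glutamate transporter gene Slc17a7 (-6.54 ± 0.46) were among the lowest. All 8 fenestrated genes were higher (median 5.11, camera adjusted p = 6.26e-17, and adjusted p = 0.0714 with an estimated correlation), and 8 of 8 when scaled on the pan-endothelial genes (median 2.82). Of 17 barrier genes 11 were lower, with Spock2 at -4.84, Slc38a3 at -4.43 and Mfsd2a at -3.48, and 2 were higher (adjusted p = 0.00156, and adjusted p = 0.405 with an estimated correlation). Slc38a3 had not passed in Retina Positive over Input. Under that scaling 17 of 17 barrier genes were lower, but so were most of all 7270 genes. All 19 pan-endothelial genes were higher, with Emcn at 4.63 (median 2.16, and -0.105 under that scaling, adjusted p = 1.95e-07, and adjusted p = 0.32 with an estimated correlation). Tspan12 was higher by 2.45 ± 0.22, and by 0.16 with an adjusted p of 0.578 under that scaling. Microglial genes (7 of 7, C1qa 4.44), fibroblast genes (3 of 3) and choroid plexus genes (5 of 6) were higher with adjusted p = 0.00156, 0.0142 and 0.00246, and adjusted p = 0.288, 0.215 and 0.215 with an estimated correlation. The rank-based test gave 0.0554 for the fibroblast list. Under the pan-endothelial scaling 5 of 7 microglial (median 1.58) and 1 of 3 fibroblast genes (0.408) were higher. Of choroid plexus genes 2 were higher and 1 lower (0.581). Photoreceptor genes (3 of 3) and neuronal genes (3 of 5) were lower (adjusted p = 3.93e-05 and 0.00919, and adjusted p = 0.213 and 0.32 with an estimated correlation).

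All 80 ribosomal protein genes were higher in Choroid Positive than in Retina Positive (median 1.39, adjusted p = 9e-13, and adjusted p = 0.405 with an estimated correlation), but 62 were lower under the pan-endothelial scaling (median -0.983). Caveolar, arterial, venous, tip cell, MHC class I and immediate early genes were higher (adjusted p = 0.000774, 0.000507, 0.0385, 0.0125, 0.000311 and 0.00135, and adjusted p = 0.288, 0.32, 0.405, 0.32, 0.334 and 0.215 with an estimated correlation). Of these the tip cell median alone stayed positive under that scaling (0.32), and the other medians were -0.503, -0.0462, -0.313, -0.129 and -0.275. Of 11 arterial genes 10 were higher, and 10 with 1 lower adjusted over the list alone. Of 7270 genes 4536 passed, 2284 higher and 2252 lower, and 168 and 6440 under that scaling, which moved the median of all genes from -0.0257 to -2.44.

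Retina Positive held more rod transcripts than Brain Positive. Pde6a was higher by 8.92 ± 0.39, Reep6 by 8.07 ± 0.22 and Rom1 by 6.86 ± 0.30 (n = 3, adjusted p = 6.94e-08 for Pde6a by edgeR). Ptgds was lower by -8.28 ± 0.51, Col1a2 by -7.61 ± 0.26, Apod, an apolipoprotein gene, by -5.94 ± 0.48, Igf2 by -5.67 and Igfbp2 by -4.65. Barrier genes gave no call (4 of 17 higher, such as Slc16a1 at 1.45, and 5 lower, such as Slc22a8 at -2.71, adjusted p = 0.687), and neither did pan-endothelial genes (8 of 19 lower, 7 adjusted over the list alone, adjusted p = 0.151), with the barrier median of -0.149 turning to 0.309 when scaled on the pan-endothelial genes. Photoreceptor genes (3 of 3) were higher, and fibroblast genes (3 of 3) and microglial genes (7 of 7, C1qb -4.10) were lower, with adjusted p = 3.88e-08, 1.26e-05 and 0.0041, and adjusted p = 0.0974, 0.0974 and 0.488 with an estimated correlation. The tip cell gene Angpt2 was lower by -2.83 ± 0.24. Of 80 ribosomal protein genes 74 were lower, 75 adjusted over the list alone (median -0.834, adjusted p = 9.3e-08, and adjusted p = 0.787 with an estimated correlation), against 3 lower under the pan-endothelial scaling. Oligodendrocyte genes (3 of 4) were lower and retinal interneuron (2 of 3) and pigment epithelium genes (2 of 5, with 1 lower) higher, with adjusted p = 0.0295, 0.0478 and 0.029, and adjusted p = 0.488, 0.488 and 0.237 with an estimated correlation. These 3 calls were lost by the rank-based test (adjusted p = 0.053, 0.105 and 0.345). The pigment epithelium median was 0.326. Of 7270 genes 4152 passed, 2148 higher and 2004 lower (51.7% higher), and 3024 and 557 (84.4% higher) under that scaling, which moved the median of all genes from 0.00401 to 0.616.

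**Figure D3:**
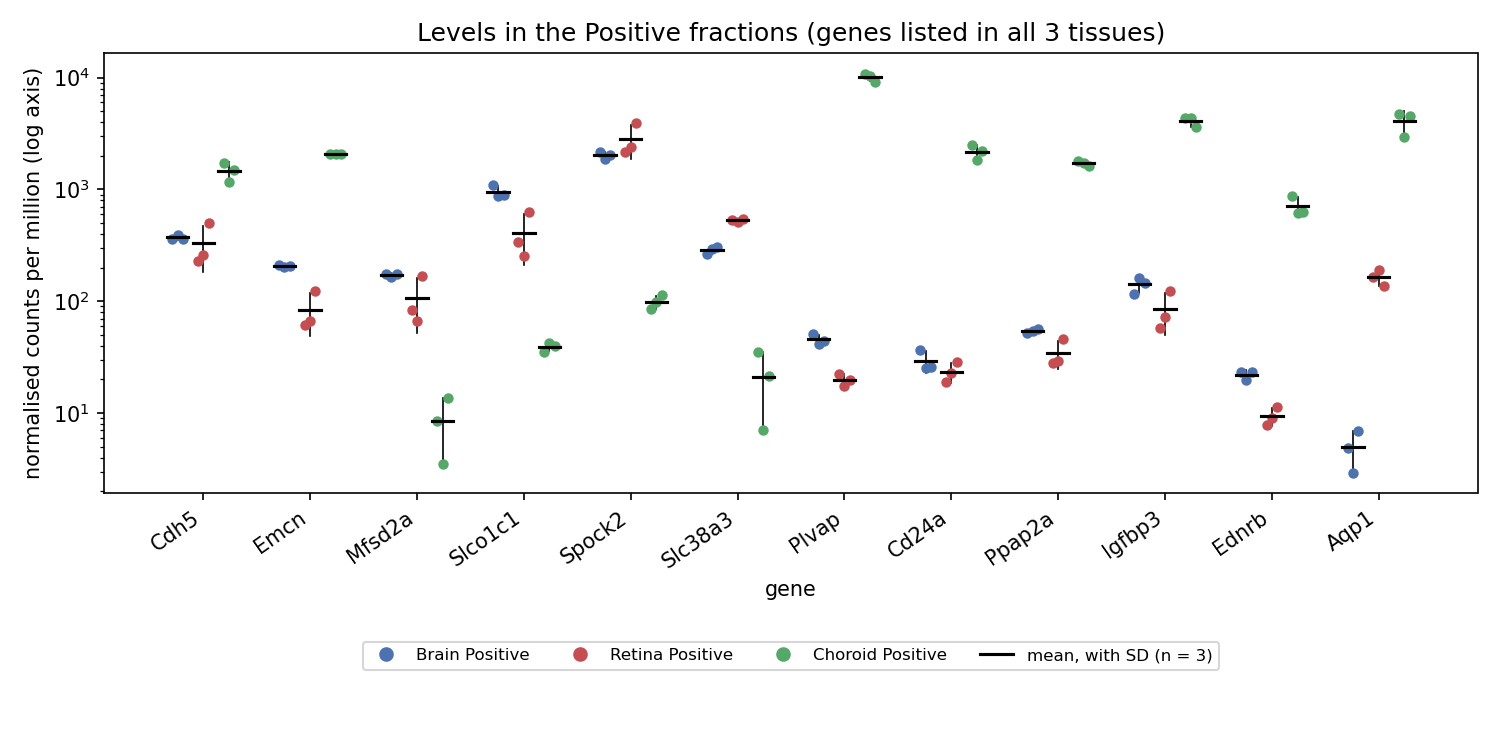
Normalised CPM (log axis) of 12 genes in the Positive libraries of each tissue, with bars for the mean and lines for the SD over 3 libraries. Plvap averaged 10150 in Choroid, 45.5 in Brain and 19.8 in Retina, and Mfsd2a averaged 8.53, 172 and 106.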

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

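The tests of the fibroblast pattern, the Choroid Input share, the carry-over in Choroid and gene length and GC content were chosen only after seeing the result. The genes listed in the next 3 paragraphs were picked out because Positive over Input differed between tissues by an interaction test.

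Choroid minus Brain had 3769 such genes. Aqp1 (3.81), Prickle2 (3.59), Six3 (3.51), Mcam (3.40), Plvap (2.34), Cd24a (2.23), Egr1 (2.42) and Nr4a1 (2.28) were higher. Edn3 (-7.66), Slco1c1 (-7.16), Slc22a8 (-7.11), Mfsd2a (-4.91), Slc2a1 (-4.18, with -0.42 and an adjusted p of 0.26 between the Positive fractions), Fzd4 (-3.43, though higher in Choroid between the Positive fractions at 1.82), Apcdd1 (-4.93), Col1a2 (-6.89) and Fbln1 (-7.04) were lower. Between these Positive fractions the pan-endothelial median was 1.59. Scaled on the pan-endothelial genes, 0 of 11 Wnt/beta-catenin genes, a list that holds Fzd4, were higher in Choroid Positive and 7 were lower. Of all 7270 genes 6367 were lower under that scaling.

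Choroid minus Retina had 3272. Aqp1 (3.66), Pdia5 (3.50), Cd24a (2.68), Plvap (2.67), Jun (2.02) and Nr4a1 (2.02) were higher, and Slco1c1 (-8.06), Stra6 (-7.42), Slco1a4 (-5.91), Slc7a5 (-5.65), Mfsd2a (-7.40) and Slc2a1 (-2.73, but -0.15 with an adjusted p of 0.693 when scaled on the pan-endothelial genes) were lower.

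Retina minus Brain had 2170. Mal (4.35), Fam107a (3.71), Cd34 (2.53), Pde2a (2.44), Mfsd2a (2.49) and Mbp (2.12) were higher, though between the Positive fractions Mal (-0.09), Mfsd2a (-0.69) and Slc2a1 (-0.01) did not pass and Mbp was lower in Retina (-3.48), and Kdr (-4.34), Prom1 (-4.27), Ptgds (-4.14), Igf2 (-3.91), Pde6a (-3.76), Alpl (-3.65), Slc2a1 (-1.45), Col1a2 (-3.96) and Fbln1 (-4.45) were lower. Between the Positive fractions Pde6a was higher in Retina, by 8.92.

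Fibroblast genes were higher in Brain Positive (8 of 8, median 4.10) and lower in Choroid Positive (7 of 7, median -2.68). RNA carried over from other brain cells is argued against, since the highest median among the neuron, oligodendrocyte and microglia lists was -1.29. Tagged ribosomes in pericytes cannot be told apart, since 5 pericyte genes picked from the mural list had a median of -1.01 while 5 of the 12 mural genes rose, Pdgfrb and Vtn among them. Fibroblasts that travel with vessels may contribute, but the SD of the log2 fibroblast share over that of the endothelial share, 7.32 from 3 libraries, could not tell this apart. Tagging of fibroblasts and collagen transcripts made by the endothelium itself both stay open.

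Pan-endothelial fold changes were smaller in Choroid (median 2.80) than in Brain (5.12) and Retina (6.19). An effect of low counts on the estimates is argued against, since Brain and Retina thinned to Choroid depth still exceeded Choroid by at least 2.25. Thinning keeps the ratio of Positive to Input on average, so it could not test other effects of depth, such as which genes were listed. Carry-over of RNA from other cells in Choroid cannot be told apart, since the median difference of genes of other cell types between Choroid and Brain, over members that went both ways, was -0.894 and turned to 1.12 when scaled on the pan-endothelial genes. That scaling shifted the median of all genes upward as well, so the turn comes from the scaling, and the answer depends on which scaling holds. A larger endothelial share in Choroid Input likely contributes, since that share exceeded the share in Brain Input by 3.57 on the log2 scale. In Positive the share was larger in Choroid as well, by 1.52 (2.82% ± 0.525 against 0.97% ± 0.0244 in Brain, SD, n = 3). That argues against a smaller endothelial share in Choroid Positive than in Brain Positive as the source of the gap. How much of the gap in barrier genes is left beyond the larger share in Choroid Input, and how much of the barrier transcripts in Choroid Input came from pigment epithelium, stays open.

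In Retina Positive 7 cone genes of the pattern fell (median -2.10), as did 3 of the other 7 cone genes, while of 14 rod genes edgeR called 0 (2 at an unadjusted p under 0.05) and DESeq2 1. Gene length and GC content are argued against, since random genes of like length and GC content gave a cone minus rod difference of 0.0455 (95% of 10000 draws from -0.317 to 0.421). The median of the other 7 cone genes, -0.537, lay at percentile 0.02 of 10000 random lists of like expression. That argues against a chance draw of unrelated genes. Random lists do not share the correlation between genes of the same cell type, so a chance shift of cone genes together cannot be told apart. Whether a single library pair carries it cannot be told apart: 3 of 3 pairs showed it, but the genes had been picked for Positive values all on the same side of Input. Whether rod RNA may stay with the beads more than cone RNA, or another source holds rod transcripts, stays open.

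In each of the 9 comparisons the true grouping was the 1 of 10 splits with as many genes called, and the highest other split had 0. With 10 splits the smallest share is 0.1, too few to exclude chance at 0.05. In the comparisons within a tissue, 4 of these splits part every same-numbered pair of Input and Positive libraries, so fewer still respect the shared homogenate.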

How the results depend on the processing

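Scaling on the pan-endothelial genes, thinning, and the use of all genes shared by Brain and Retina were chosen only after seeing the result. DESeq2 size factors, the DESeq2 Wald test, no filter and the authors' factors kept every total of genes called within 1.5 times, though DESeq2 size factors turned the Retina minus Brain split from 802 higher and 1368 lower to 1402 and 885. The replicate block gave 11054 (Brain), 3085 (Retina), 2998 (Choroid), 3871 (Choroid minus Brain), 3382 (Choroid minus Retina) and 2429 (Retina minus Brain) genes. Of single-gene results under the named-gene rule, 383 kept their status with the block, passing or not, 1 lost a call and 8 gained a call. No list call changed with the block beyond those given with a block value in the report. With DESeq2 size factors 438 of 440 single-gene results kept their status and 2 lost a call.

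The stricter filter, which tests fewer genes by construction, gave 5729 (Brain), 1952 (Retina), 1802 (Choroid), 2011 (Choroid minus Brain), 1634 (Choroid minus Retina), 2236 (Choroid Positive against Brain Positive), 2615 (Choroid Positive against Retina Positive) and 2232 (Retina Positive against Brain Positive), with 367 shared higher and 53 shared lower genes. An adjusted p under 0.01 left 1733 (Retina), 1262 (Retina minus Brain) and 36 shared lower genes. A change of at least 2-fold left 4607 (Brain), 1170 (Retina), 2297 (Choroid minus Brain), 1854 (Choroid minus Retina), 1022 (Retina minus Brain), 1923 (Choroid Positive against Brain Positive), 2657 (Choroid Positive against Retina Positive) and 1822 (Retina Positive against Brain Positive), with 368 shared higher and 9 shared lower genes. The pan-endothelial scaling gave 6004 (Choroid minus Brain), 6518 (Choroid minus Retina), 1376 (Retina minus Brain) and 6509 (Choroid Positive against Brain Positive). All genes shared by Brain and Retina gave 6072 (Retina minus Brain) and 8725 (Retina Positive against Brain Positive), with more genes tested. Thinning left 93 shared lower genes. With an estimated correlation 7 of 109 list calls over the 9 comparisons stayed, none of them between Positive fractions. The rank-based test lost 9 list calls, each given with its value in the report, and gained 15. The share and the median of a list had opposite signs for lymphatic (0.35, -0.514) and mural genes (2.73, -0.32) in Brain and skeletal muscle genes (-0.8, 0.153) in Retina. In Brain Vtn rose from 103.5 to 1234 CPM while 6 of 12 mural genes fell, and for the other 2 lists the cause was not tested.

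Leaving out a library gave 10189 to 10931 (Brain), 1836 to 3637 (Retina), 2167 to 3041 (Choroid), 3331 to 4086 (Choroid minus Brain), 2881 to 3666 (Choroid minus Retina), 1661 to 2273 (Retina minus Brain), 3067 to 4305, 3990 to 4861 and 3328 to 4304 (the Positive comparisons), 572 to 726 shared higher and 67 to 172 shared lower genes. Pseudocounts do not apply to counts and were not run. Thinned to Choroid depth, Brain gave 8660 and Retina 2297 genes.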

Other observations

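The Retina Xist comparison was chosen only after seeing the result. Xist counts in Retina replicates 1, 2 and 3, not scaled to library totals, were 18.5, 18057 and 14888 in Input and 96.2, 2282 and 7783 in Positive.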
